A study of Mus musculus with 6 samples.

How the data were processed

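Bulk RNA-seq was measured in 6 libraries of whole pancreas from NMRI mice at postnatal day 7, 3 per group. Controls carried a Cre recombinase at 1 allele of Ptf1a, a transcription factor gene of pancreatic progenitors and acinar cells. Mutants carried in addition a transgene that makes Prox1 and LacZ once Cre has removed a stop cassette. Per the labels' protocols, RNA came from individual pancreata kept in an RNA stabilising solution and was extracted with TRIzol and a column kit, and per the series' design text a poly(A) mRNA kit was used for the libraries. The design text speaks of pools for the controls and of individual pancreata for the mutants, so whether a control library is 1 animal is left open.

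The deposited values are read counts per gene symbol, whole numbers for 23337 genes in each library. No entry held a total or unassigned reads. Per the submitters' processing notes, the tools were cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2, and the genome build was mm10; the versions of STAR and DESeq2, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies (trypsinogens, amylases, many ribosomal protein genes) and of genes that overlap on opposite strands are therefore uncertain. LacZ was not analysed here.

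Counts were taken as deposited. Genes were kept by edgeR's filterByExpr with the group as factor (minimum count 10, minimum total count 15), which left 13017 genes. Libraries were scaled by TMM factors, and CPM values in the text use these factors. The gene test was edgeR 4.0.16's quasi-likelihood F test with robust estimation, mutant against control with no other covariate, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors were taken as the log2 fold change divided by the square root of its F value. R 4.3.3 and limma 3.58.1 were used. The share of counts in the digestive enzyme list was compared by an exact two-sided permutation test over 20 assignments, whose smallest p is 0.1.

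Before the data were examined, 36 gene lists were fixed for acinar cells, other cell types of a whole pancreas, neighbouring tissues, and stress, signalling and growth programmes. Of 745 planned members, 3 were absent and 8 were found under another symbol; no gene was in more than 1 list. The 35 lists with at least 4 tested members were tested by limma's camera on log2 CPM (prior count 2, preset correlation 0.01) with Benjamini-Hochberg adjustment over these lists. Camera asks whether a list's genes moved relative to the other genes. For each list the members past the gene test were counted with the adjustment over all genes and with the adjustment over the list alone. Intervals of list medians came from 10000 bootstrap draws of the members, which treat members as independent.

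Genes named in the text followed a rule fixed before the data were examined. It took Prox1, Ptf1a, Amy2a5, Cpa1, Cela1, Sox9, Krt19, Ins2 and Gcg in every case. It took the 10 largest rises and the 10 largest falls by log2 fold change among genes past the threshold with a mean log2 CPM of at least 2 and no overlap of the groups, without predicted or clone-named symbols. For each list it took up to 3 members past the threshold with the smallest p, or the member with the highest mean expression where none passed. Other genes were named after their values were seen, and the text says so. The result of 1 gene that the rule named is not reported here. Gene positions and Ensembl identifiers are from GENCODE vM21 on GRCm38, the assembly of mm10.

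The gene test was checked on simulated counts drawn from the means and library sizes of these libraries (12862 genes in that step). For mutant against control, it recovered 25.8% of genes changed 1.5-fold, 68.3% of those changed 2-fold and 96.8% of those changed 4-fold, and 7 of its 132 calls (5.3%) were false. Libraries were compared within groups before averaging, and none were identical: the chi-square per gene between pairs ran from 5.54 to 19.18. Alternatives were other scalings (DESeq2's size factors, library size alone, TMM without the acinar product lists), other filters, DESeq2 1.42.0 and limma-voom, non-robust estimation, a replicate block, a threshold of 0.01, leaving out each library, and for lists fry and camera with an estimated correlation. Leaving out control 1 together with mutant 2, leaving out genes on the X and Y chromosomes, and adding 6 further trypsinogen genes to the enzyme share were chosen after the data were seen.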

Results

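Transcript levels were compared in whole pancreas of mice at postnatal day 7, an age at which most of the gland is made of acinar cells, the cells that make digestive enzymes. There were 3 control libraries (Ptf1a-Cre alone) and 3 mutant libraries (Ptf1a-Cre with the conditional Prox1 transgene). Control libraries 1, 2 and 3 held 7304727, 9522106 and 10773223 counts. Mutant libraries 1, 2 and 3 held 9957737, 7729161 and 9933559. Digestive enzyme genes took 55.62 to 61.82% of the counts of each library, which left 2788989 to 4280013 counts for all other genes. That the libraries stand for separate animals rests on the labels, except that control 1 differed from the others in sex-linked counts. For the controls the design text speaks of pools, so p-values of the gene test measure the spread between these samples. Camera p-values rest on the preset correlation of 0.01 between list members. With an estimated correlation 0 of the 35 lists were called. Control 1 held 7110 Xist counts and 0 counts of 4 Y-linked genes, whereas the other 5 libraries held 1 to 4 Xist counts and 136 to 556 counts of each Y-linked gene. These counts argue against a pool of both sexes in any control library, and leave a pool of 1 sex open.

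Prox1, a homeodomain transcription factor that is low in mature acinar cells, is the gene expressed from the transgene. It had 72, 71 and 95 counts in the controls and 268, 270 and 310 in the mutants. Its level rose from 9.27 ± 1.5 to 29.3 ± 3.25 CPM (SD, n = 3 each), a 3.18-fold change (log2 fold change 1.67, SE 0.15, edgeR adjusted p = 7.33e-05). Prox1 (ENSMUSG00000010175) lies on chromosome 1 from 190118035 to 190170714 on the minus strand of GRCm38. The counts do not separate transgenic from endogenous transcripts, and an antisense gene, Prox1os, overlaps the locus. Ptf1a, the locus that carries Cre in both groups, had 19.8 ± 1.85 CPM in controls and 14.9 ± 0.529 in mutants (log2 fold change -0.40, SE 0.13, n = 3 each) and did not pass the threshold (edgeR adjusted p = 0.163).

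**Figure D1:**
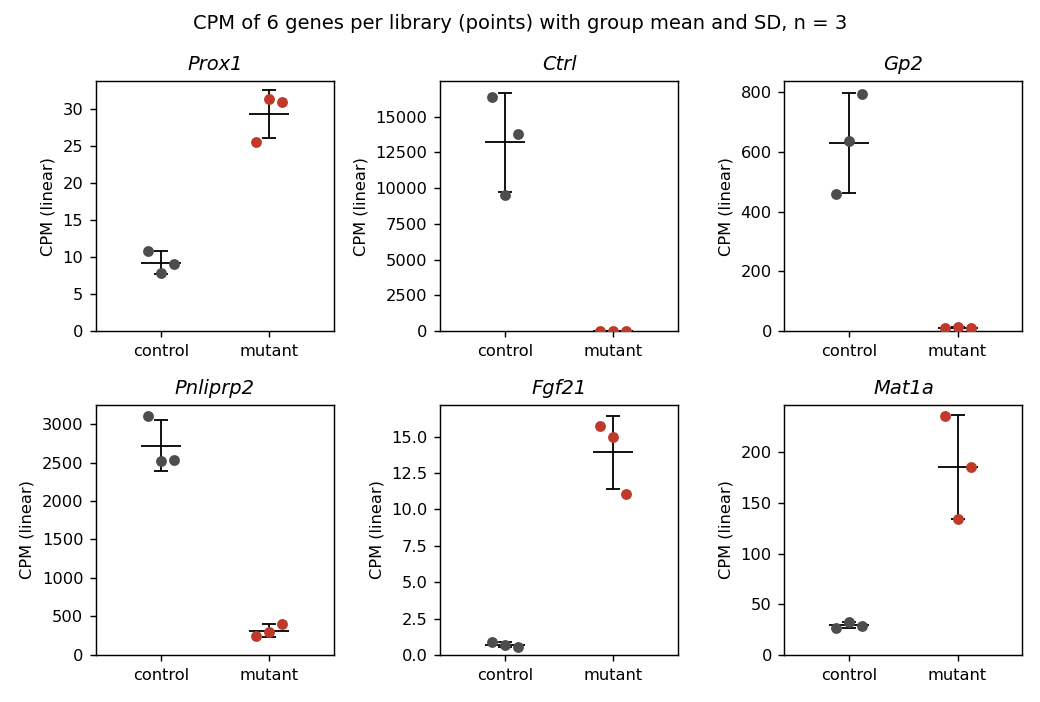
CPM (linear axes from 0) of 6 genes in each control (grey) and mutant (red) library; horizontal bars are group means and error bars SD, n = 3. Prox1, Fgf21 and Mat1a were higher in every mutant library than in any control, and Ctrl, Gp2 and Pnliprp2 were lower, with Ctrl falling from 13210 to 3.76 CPM on average.

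The series asks which genes respond when acinar cells express Prox1 ectopically. Counts of whole pancreas do not show in which cells Prox1 or other genes changed. Of 13017 tested genes, 297 differed between mutant and control, 82 higher and 215 lower in the mutants (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Among them 154 changed at least 2-fold, 45 upward and 109 downward. In all 297 the mutant and control values did not overlap, as in 18.98% of all tested genes, where chance gives 10%. The biological coefficient of variation was 14.2%. Scaling by library size alone moved the median log2 fold change of all genes from 0.004 to 0.17 and turned the split to 246 higher and 149 lower, so directions of small changes are relative to the scaling. The number of differing genes was 156 without control 2, 180 without control 3 and 170 without mutant 1. Without control 1 and mutant 2, a pair chosen after the data were seen, it was 630. Control 1 was the only library with high Xist and no Y-linked counts, so sex differs in part between the groups. Without control 1 the test called 232 genes, 193 of them among the 297. Leaving out genes on the X and Y chromosomes, also chosen after the data were seen, gave 293. That count cannot show effects of sex on genes of other chromosomes.

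**Figure D2:**
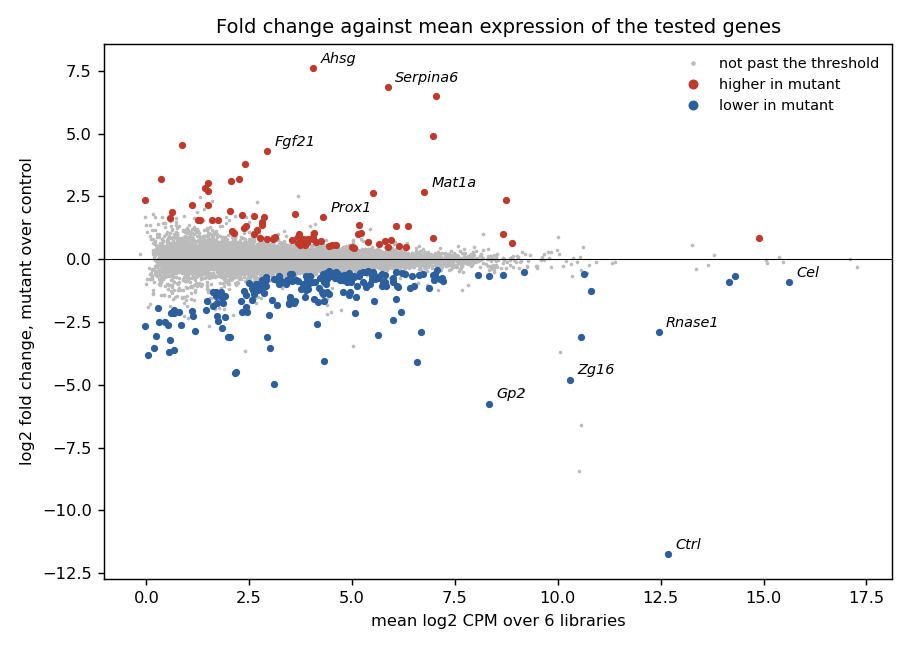
Log2 fold change of mutant over control against mean log2 CPM over the 6 libraries for the tested genes; red and blue points are the 82 higher and 215 lower genes past the threshold, and grey points are the rest. The change of largest size was that of Ctrl, at -11.76; with scaling by library size alone, higher genes outnumber lower ones, 246 to 149.

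Some digestive enzyme genes fell in the mutants, while 3 of 6 trypsinogen genes outside the fixed list rose. Ctrl, which encodes a chymotrypsin-like protease, fell from 13210 ± 3457 to 3.76 ± 2.77 CPM (log2 fold change -11.76, SE 0.70, n = 3 each, edgeR adjusted p = 0.0013). It had 20 to 73 counts in the mutants against 86046 to 143311 in the controls. The lipase-related gene Pnliprp2 fell 8.63-fold (log2 fold change -3.11, SE 0.20, edgeR adjusted p = 6.07e-06). The ribonuclease gene Rnase1 fell 7.51-fold (-2.91, SE 0.19) and the kallikrein gene Klk1 fell 2.43-fold (-1.28, SE 0.15). The bile salt-stimulated lipase gene Cel, colipase Clps and pancreatic lipase Pnlip, named after their values were seen, fell by 0.93, 0.66 and 0.66 on the log2 scale. The calls of Clps and Pnlip were lost with scaling by library size alone (edgeR adjusted p = 0.0676 and 0.0743). They were also lost without any 1 library except mutant 2 for Clps (0.0654 to 0.236) and mutant 3 for Pnlip (0.0735 to 0.223). In contrast Cpa1, a carboxypeptidase gene, had 36700 ± 561.5 CPM in controls and 32830 ± 3767 in mutants (log2 fold change -0.16, SE 0.13). The elastase gene Cela1 had 13920 ± 2462 and 11930 ± 392.7 CPM (-0.22, SE 0.15); neither passed the threshold. Of 25 tested members of the list, 0 rose, 7 fell and 18 did not pass; adjusted over the list alone, 2 rose and 13 fell. The list's median log2 fold change was -0.65 (camera adjusted p = 6.92e-09, camera adjusted p = 0.403 with an estimated correlation, fry adjusted p = 0.0237). These genes took 61.1 ± 0.69% of control counts and 57.0 ± 1.35% of mutant counts. The difference was -4.08 percentage points (exact two-sided permutation p = 0.1, the smallest possible, n = 3 each). Of 6 trypsinogen genes that the list did not hold, named after their values were seen, 3 rose, 0 fell and 3 did not pass. 2210010C04Rik rose from 21850 ± 1929 to 38960 ± 2816 CPM (log2 fold change 0.83, SE 0.13, n = 3 each, edgeR adjusted p = 0.00428). Gm2663 rose 29.5-fold (edgeR adjusted p = 3.77e-05) and 1810009J06Rik rose 90.3-fold (0.0416). The call of 1810009J06Rik was lost without any 1 control or mutant 3 (0.114 to 0.204) and with no filter on low counts (0.0588). Gm5771 had 97.7, 4187 and 4443 CPM in controls 1, 2 and 3 and 5.71 to 10.9 in the mutants (log2 fold change -8.42, edgeR adjusted p = 0.177). Without control 1, the control nearest the mutants, the log2 fold change was -9.0 (edgeR adjusted p = 4.68e-07). Gm10334 had 289 ± 35.2 and 122 ± 57.5 CPM (-1.24, edgeR adjusted p = 0.206). Without mutant 1, the mutant nearest the controls, its log2 fold change was -1.69 (edgeR adjusted p = 0.000409). Gm5409 had 617, 3.65 and 2.79 CPM in controls 1, 2 and 3 and 159 to 480 in the mutants (log2 fold change 0.48, SE 2.11). Without control 1 its log2 fold change was 6.49 (edgeR adjusted p = 0.102). With these 6 genes added, a choice made after the data were seen, the share was 63.5 ± 0.27% in controls and 61.2 ± 1.45% in mutants. That difference was -2.25 percentage points (exact two-sided permutation p = 0.1, n = 3 each). All 12 trypsinogen genes took 7.71 ± 0.43% of control counts and 10.2 ± 0.39% of mutant counts (exact two-sided permutation p = 0.1, n = 3 each), and reads may be split among their near-identical copies. Without control 1 and mutant 2, 2 libraries per group were left. The log2 fold changes of Ctrl and Pnliprp2 were then -11.33 and -2.98 (edgeR adjusted p = 0.0686 and 0.103). The amylase gene Amy2a5, which has near-identical copies, held 0 to 4 counts per library and was not tested. In control 1 the trypsinogen gene Prss1 stood at 118 CPM, against 4304 and 4557 in controls 2 and 3 and 11.5 to 42.6 in the mutants. Try4 stood at 297.7 CPM in control 1, 3143 and 2467 in controls 2 and 3 and 127.5 to 183.2 in the mutants. Both were chosen after their values were seen, and neither passed with all 6 libraries (edgeR adjusted p = 0.246 and 0.25). Without control 1 the log2 fold changes were -7.18 and -4.21 (edgeR adjusted p = 0.0382 and 4.93e-06). That fit leaves out the control nearest the mutants, so it cannot show a fall by genotype.

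Ctrl (ENSMUSG00000031896) lies on chromosome 8 from 105932003 to 105933862 on the minus strand of GRCm38. Psmb10, which encodes an immunoproteasome subunit, lies from 105935735 to 105938444 on the same strand, 1873 bases away. On the other side Pskh1, chosen after its values were seen, lies nearer, 0.2 kb away on the plus strand. Pskh1 did not pass (log2 fold change -0.24, edgeR adjusted p = 0.47). Psmb10, chosen after its values were seen, fell from 89.0 ± 11.4 to 10.9 ± 2.94 CPM (log2 fold change -3.03, SE 0.17, n = 3 each, edgeR adjusted p = 6.07e-06). None of the other 11 tested genes within 200 kb passed the threshold, and their log2 fold changes ran from -0.27 to 0.21.

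Components of the zymogen granule, the store of digestive enzymes in acinar cells, were lower in part. Gp2, the major glycoprotein of the granule membrane, fell 54.1-fold, from 630 ± 168 to 11.7 ± 2.32 CPM (log2 fold change -5.76, SE 0.25, n = 3 each, edgeR adjusted p = 5.07e-06). Zg16, a granule matrix lectin, fell 27.7-fold (-4.79, SE 0.39). Fgf21, a secreted hormone of acinar cells and liver, rose 19.7-fold from 0.714 ± 0.169 to 13.9 ± 2.49 CPM (log2 fold change 4.30, SE 0.26). The water channel gene Aqp8 rose 2.50-fold (1.32, SE 0.11). The zymogen granule and acinar secretion list also holds genes that are not granule components, such as Fgf21 and Aqp8. Of its 25 tested members, 2 rose, 6 fell and 17 did not pass. Adjusted over the list alone, 3 rose and 11 fell. The median log2 fold change was -0.24 (camera adjusted p = 3.39e-05; adjusted p = 0.403 with an estimated correlation and 0.0677 by fry). Without control 1 and mutant 2, the log2 fold change of Zg16 was -4.54 (edgeR adjusted p = 0.146).

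Acinar transcription factor genes were lower as a list. Of 8 members, 0 passed the threshold over all genes and 4 fell when adjusted over the list alone. Their log2 fold changes ran from -0.53 to -0.09, the latter for Nr5a2, which stood at 0.07 with scaling by library size alone. Rbpjl, the Ptf1a partner of mature acinar cells, had 416 ± 59.4 CPM in controls and 289 ± 14.9 in mutants (log2 fold change -0.53, SE 0.13, n = 3 each, edgeR adjusted p = 0.0575); it overlaps Matn4 on the other strand. The list's median was -0.31 (camera adjusted p = 3.39e-05; adjusted p = 0.403 with an estimated correlation; fry adjusted p = 0.0237), and -0.14 with scaling by library size alone.

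Further large falls lay outside these lists. The retinol transport gene Stra6 fell 31.7-fold, the glycosyltransferase gene Galntl6 fell 23.2-fold, the water channel gene Aqp12 of acinar cells fell 17.2-fold, the pepsinogen gene Pga5 fell 16.4-fold and the bile acid receptor gene Nr1h4 fell 11.6-fold. Their edgeR adjusted p ran from 9.38e-08 for Pga5 to 0.000776 for Galntl6. Pga5 went from 37.4 ± 3.33 to 2.27 ± 0.171 CPM and Aqp12 from 182 ± 15.6 to 10.5 ± 3.70 CPM (SD, n = 3 each).

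Genes of the Reg family, secreted lectins linked to pancreatic injury, moved in both directions. Reg2 fell 22.3-fold (log2 fold change -4.48, SE 0.57, edgeR adjusted p = 0.00366) and Reg3d fell 4.33-fold (-2.11, SE 0.13). Reg3b rose 3.81-fold, from 1.56 ± 0.369 to 6.02 ± 0.979 CPM (1.93, SE 0.27, n = 3 each). Of 9 tested members of the Reg and acute phase list, 1 rose, 4 fell and 4 did not pass; adjusted over the list alone, 1 rose and 5 fell. The median was -0.90 (camera adjusted p = 0.0121; adjusted p = 0.629 with an estimated correlation). The camera adjusted p was 0.0761 without control 1.

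Serpina6, which encodes corticosteroid-binding globulin, had one of the largest rises, from 1.01 ± 0.299 to 115 ± 57.6 CPM (log2 fold change 6.83, SE 0.60, n = 3 each, edgeR adjusted p = 0.00889). The vitamin D-binding protein gene Gc rose 5.14-fold from 139 ± 40.7 to 714 ± 79.7 CPM (2.36, SE 0.21). Ahsg, which encodes fetuin A, had 0, 4 and 0 counts in the controls and 513, 123 and 331 in the mutants. Its fitted log2 fold change was 7.60 (SE 1.03, edgeR adjusted p = 0.0403, and 0.0789 with no filter on low counts). The methionine adenosyltransferase gene Mat1a rose 6.32-fold, the aldehyde dehydrogenase gene Aldh1b1 rose 6.17-fold and the protease inhibitor gene Pzp rose 13.8-fold. The cadherin family gene Fat3 rose 9.18-fold and the keratin gene Krt17 rose 8.56-fold. Of 20 members of the hepatocyte list 5 were tested, of which 2 rose (Ahsg and the vitronectin gene Vtn, log2 fold change 0.63, SE 0.13), 0 fell and 3 did not pass. Adjusted over the list alone, 2 rose and 1 fell. The list's median was 0.63 (camera adjusted p = 0.0105; adjusted p = 0.423 with an estimated correlation). Albumin, Alb, the most abundant hepatocyte transcript, chosen after its values were seen, had a log2 fold change of 1.31 (edgeR adjusted p = 0.399). Adjusted p lay above the threshold for Ahsg without control 1, 2 or 3 or mutant 3 (0.112 to 0.324), and for Serpina6 without any 1 control (0.0587 to 0.0746). The same held for Fat3 without control 2, control 3 or mutant 1 (0.0591 to 0.118) and for Vtn without control 2, control 3, mutant 1 or mutant 3 (0.127 to 0.177). Without control 1 and mutant 2 it was 0.14 for Serpina6 and 0.197 for Gc, with log2 fold changes of 7.14 and 2.47.

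Duct and progenitor genes did not move together. Prom1, a marker of duct and progenitor membranes, rose 1.58-fold (log2 fold change 0.66, SE 0.10, n = 3 each, edgeR adjusted p = 0.00313). The duct transcription factor gene Sox9 (-0.42, SE 0.13, edgeR adjusted p = 0.169) and the duct keratin gene Krt19 (-0.59, SE 0.15, edgeR adjusted p = 0.0882) did not pass; without control 1 the adjusted p of Krt19 was 0.013. Of 17 duct genes, 1 rose, 0 fell and 16 did not pass; adjusted over the list alone, 3 rose and 3 fell. The median of -0.12 turned to 0.04 with scaling by library size alone (camera adjusted p = 0.863). In the acinar metaplasia and injury list Muc6, a gastric mucin gene, rose 7.05-fold and Gkn3, a gastrokine gene, fell 8.53-fold. The other 11 of 13 members did not pass; adjusted over the list alone, 4 rose and 3 fell (camera adjusted p = 0.996). Pdx1, a transcription factor gene of pancreatic progenitors and beta cells, fell 2.24-fold (-1.16, SE 0.22, edgeR adjusted p = 0.0156). The fetal chromatin gene Hmga2 fell 4.12-fold (-2.04, SE 0.31). Hmga2 overlaps 9230105E05Rik on the other strand, which also fell. These were the 2 that fell among 15 embryonic progenitor and fetal genes, with 0 that rose, 13 that did not pass and again 2 that fell when adjusted over the list alone (camera adjusted p = 0.328). The adjusted p of Pdx1 was 0.0552 without control 1 and 0.075 without mutant 1.

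Islet hormone genes did not pass the test. Ins2 had 1741 ± 531.9 CPM in controls and 1288 ± 60.6 in mutants (log2 fold change -0.44, SE 0.19, edgeR adjusted p = 0.37). Gcg had 886 ± 247 and 1149 ± 147 CPM (0.38, SE 0.20, edgeR adjusted p = 0.484, n = 3 each). Nkx2-2, an endocrine transcription factor gene, fell 3.11-fold (-1.64, SE 0.22, edgeR adjusted p = 0.00162). Of 27 islet endocrine genes 0 rose, 1 fell and 26 did not pass, with 1 that fell when adjusted over the list alone. The list's median was -0.11 (camera adjusted p = 0.0434; adjusted p = 0.714 with an estimated correlation). Control 1 stood apart, with a list median of 0.40 relative to the control mean on the log2 scale, and without it the direction turned (camera adjusted p = 0.831). The median turned to 0.06 with scaling by library size alone, and the camera adjusted p was 0.0794 without mutant 1 and 0.134 without mutant 2.

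**Figure D3:**
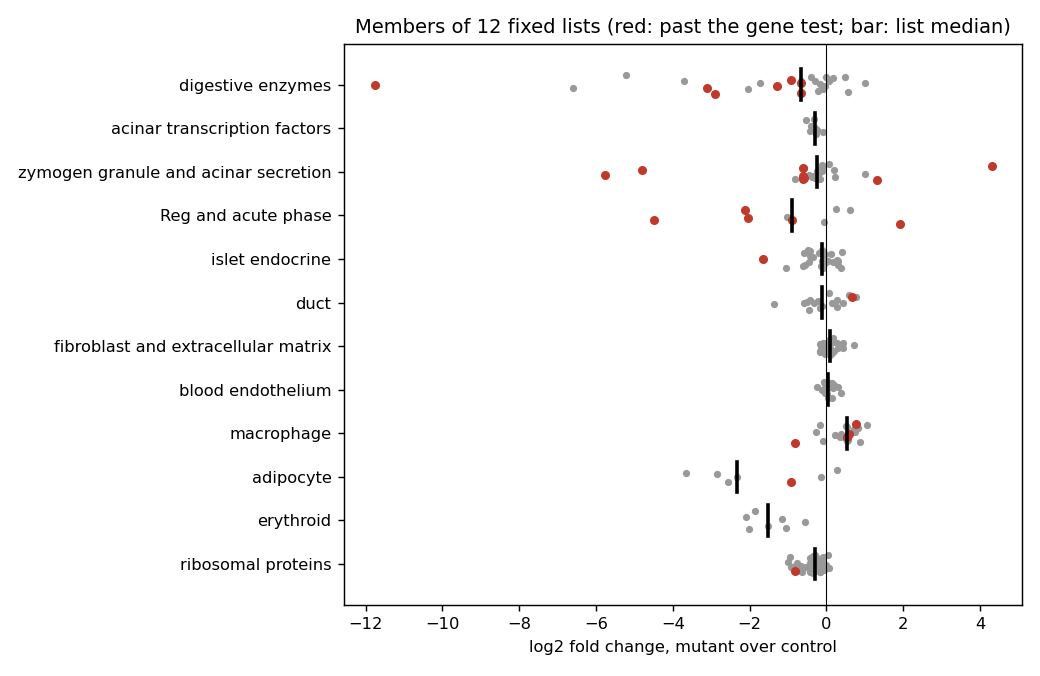
Log2 fold change of mutant over control for each tested member of 12 fixed lists; red points passed the gene test over all genes, grey points did not, and black bars are list medians. The medians of the digestive enzyme, Reg and acute phase and macrophage lists were -0.65, -0.90 and 0.53; the small negative medians of the duct and islet lists turn positive with scaling by library size alone.

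Macrophage genes were higher as a list. Mrc1, a mannose receptor gene, rose 1.44-fold (log2 fold change 0.53, SE 0.11, n = 3 each, edgeR adjusted p = 0.0252). The complement gene C1qc rose 1.5-fold (0.58, SE 0.13) while its neighbour C1qa fell 1.75-fold (-0.81, SE 0.16). Epha8, 30616 bases from C1qa, and Zbtb40 beyond it, both named after their values were seen, fell too. Whether the fall of C1qa reflects macrophages was not tested. Emr1, the F4/80 gene, named after its values were seen, rose by 0.78 on the log2 scale (edgeR adjusted p = 0.0414), and was not called without any 1 library but mutant 3 (0.0746 to 0.175). Of 20 members 3 rose, 1 fell and 16 did not pass; adjusted over the list alone, 7 rose and 1 fell. The median was 0.53 (camera adjusted p = 8e-05; adjusted p = 0.629 with an estimated correlation). The libraries' own list medians, as log2 values relative to the control mean, were -0.25, 0.10 and 0.19 in controls 1, 2 and 3 and 0.47, 0.91 and 0.16 in mutants 1, 2 and 3. Mutant 2, the highest, also held the most lymphocyte transcripts. Its B cell list median was 1.87 on the same scale, with 0.78 and 0.87 in controls 2 and 3 and -1.51, -1.56 and -1.22 in control 1 and mutants 1 and 3. Ptprc, a gene of all leukocytes, stood at 57.0 CPM in mutant 2 and at 4.69 to 14.4 CPM elsewhere (chosen after its values were seen). Without control 1 and mutant 2 the camera adjusted p was 0.414. Leaving out single libraries gave adjusted p of 0.0651 to 0.142 for Mrc1 (control 1, control 2, mutant 1 or mutant 3), 0.0574 to 0.165 for C1qc (any library but mutant 2) and 0.0835 to 0.127 for C1qa (the same 4 as Mrc1). With scaling by library size alone the adjusted p of C1qa was 0.0657.

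Interferon response and chemokine genes were higher only as lists. Of 13 interferon response genes and 7 chemokine and cytokine genes 0 passed, over all genes or adjusted over the list alone. The medians were 0.28 (camera adjusted p = 0.0261) and 0.35 (0.0385), both with an adjusted p = 0.629 with an estimated correlation. The most abundant chemokine gene, Cxcl12, had a log2 fold change of 0.22 (SE 0.26, n = 3 each), and mutant 2 held its highest level, at 81.1 CPM. Neither list was called without control 1 (camera adjusted p = 0.149 and 0.356), without mutant 2 (0.134 and 0.4) or with scaling by library size alone (0.207 and 0.217).

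Blood and fat cell genes were lower as lists, and single libraries stood apart in them. Of 6 neutrophil genes and 7 erythroid genes 0 passed, over all genes or adjusted over the list alone. The medians were -1.60 (camera adjusted p = 0.00542) and -1.51 (0.00898), with an adjusted p = 0.629 with an estimated correlation for both. Control 2 was highest, with 24.9 CPM of the neutrophil gene S100a9 against 5.49 to 11.6 elsewhere and 522 CPM of the beta-globin gene Beta-s against 94.2 to 234. Without it the camera adjusted p was 0.0668 and 0.216. In the adipocyte list Fabp4, a fatty acid-binding protein gene, fell 1.88-fold (log2 fold change -0.91, SE 0.15, n = 3 each, edgeR adjusted p = 0.00691). Of 7 members 0 rose, 1 fell and 6 did not pass, and 2 fell when adjusted over the list alone (median -2.33, camera adjusted p = 0.000638; adjusted p = 0.629 with an estimated correlation). The adiponectin gene Adipoq, chosen after its values were seen, had 20, 91 and 152 counts in the controls and 0, 21 and 0 in the mutants (edgeR adjusted p = 0.37). The adjusted p of Fabp4 was 0.0527 without control 2, 0.051 without mutant 3 and 0.0559 with scaling by library size alone. Of 5 B cell genes and 2 T and NK cell genes 0 passed either adjustment. The B cell gene Cd79b had 79 counts in mutant 2, 4 to 42 in the controls and 6 and 8 in the other mutants. The T cell gene Lck had 121 counts in mutant 2 and 8 to 29 in the other 5 libraries. The B cell list's median was 0.18 (camera adjusted p = 0.584). The T and NK list, with a median of 1.03 over Lck (1.42, SE 1.26) and Cd2 (0.64, SE 1.61), was too short for camera. Without mutant 2 the B cell list was called lower (camera adjusted p = 0.00635).

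Supporting tissues differed little. Of 25 fibroblast and extracellular matrix genes 0 passed and 1 rose when adjusted over the list alone (median 0.09, camera adjusted p = 0.106). The collagen gene Col3a1 had a log2 fold change of -0.10 (SE 0.28, n = 3 each). Of 14 smooth muscle and pericyte genes, 19 blood endothelium genes, 10 neural and glial genes and 6 mesothelium genes 0 passed over all genes. Adjusted over the list alone, 1 neural and 1 mesothelium gene fell (camera adjusted p = 0.684, 0.395, 0.584 and 0.21). Their most abundant members Acta2, Pecam1, Mbp and Upk3b had log2 fold changes of 0.09, 0.10, -0.15 and -0.36. Lymphatic endothelium is a cell type whose identity depends on Prox1. Among 11 of its genes the secreted glycoprotein gene Reln rose 2.79-fold (1.48, SE 0.26, edgeR adjusted p = 0.00889), the receptor gene Nrp2 fell 1.88-fold (-0.91, SE 0.13) and 9 did not pass, with the same counts of 1 and 1 adjusted over the list alone (median 0.26, camera adjusted p = 0.202). The adjusted p of Reln was 0.0646 without control 2 and 0.0524 without mutant 1. Leaving out single libraries called the fibroblast list higher (camera adjusted p = 0.0412 without control 2, 0.000871 without control 3 and 0.0129 without mutant 2), the lymphatic list higher (0.0263 without control 3) and the mesothelium list lower (0.000969 without control 1).

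Stress and signalling genes changed singly. The stress-response transcription factor genes Atf3 (log2 fold change 1.25, SE 0.27, n = 3 each, edgeR adjusted p = 0.0352) and Ddit3 (1.17, SE 0.27, 0.049) and the p53-induced gene Trp53inp1 (0.70, SE 0.11, 0.00428) rose. The tryptophanyl-tRNA synthetase gene Wars (-1.08, SE 0.14, 0.00183), the Notch ligand gene Jag1 (-0.68, SE 0.11, 0.00461) and the tight junction gene Cldn10 (-0.77, SE 0.13) fell, and the tight junction gene Cldn4 rose (0.89, SE 0.20). Ddit3 and Wars overlap other genes on the opposite strand. Counts of members that rose, fell and did not pass were 1, 1 and 21 for the ATF4 and amino acid response (3 and 6 adjusted over the list alone), 1, 0 and 15 for p53 targets (1 and 0), 1, 0 and 9 for immediate early genes (1 and 1), 0, 1 and 11 for the Notch pathway (0 and 1) and 1, 1 and 18 for epithelial junction genes (1 and 4). Of these lists the Notch pathway was called lower (median -0.22, camera adjusted p = 0.0195; adjusted p = 0.403 with an estimated correlation), and not without control 1 (0.054) or mutant 1 (0.0695). The camera adjusted p of the others were 0.21, 0.517, 0.21 and 0.237 in the order ATF4, p53, immediate early and junction. Without single libraries the calls of Atf3 (0.0615 to 0.179, any but mutant 2), Ddit3 (0.073 to 0.23, any but control 1), Cldn4 (0.105 to 0.192, any but mutant 2) and Cldn10 (0.0587, control 2) ended. The ATF4 (0.0206 without mutant 1), immediate early (0.0226 without control 2) and junction (0.0435 without mutant 3) lists gained a call.

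The remaining lists held no gene past the threshold, except for ribosomal proteins. Of 28 cell cycle, 25 ER chaperone, 8 Wnt target, 9 YAP target, 15 lysosome and autophagy, 20 cholesterol and lipid synthesis and 67 oxidative phosphorylation genes 0 passed, over all genes or adjusted over the list alone. Their most abundant members were near 0: Mki67 0.10, P4hb 0.05, Ccnd1 -0.13, Axl 0.02, Ctsb 0.20, Acly 0.02 and Atp5b -0.04 as log2 fold changes. Oxidative phosphorylation genes were lower as a list (median -0.16, camera adjusted p = 3.3e-06; adjusted p = 0.629 with an estimated correlation), a median that went to 0 with scaling by library size alone. The others were not called (camera adjusted p = 0.494, 0.347, 0.628, 0.362, 0.295 and 0.777 in the order given). Leaving out single libraries called the cell cycle list higher (0.0202 without control 2, 0.000759 without mutant 2), ER chaperones lower (0.0069 without control 3, 0.0206 without mutant 1) and the cholesterol list higher (0.0255 without mutant 2). Of 69 ribosomal protein genes 0 rose, 1 fell and 68 did not pass, and 21 fell when adjusted over the list alone. The median was -0.30, and -0.13 with scaling by library size alone (camera adjusted p = 1.71e-17; adjusted p = 0.583 with an estimated correlation). The 1 that fell, Rpl36 (-0.82, SE 0.19, edgeR adjusted p = 0.0487), was not called without any 1 library but mutant 2 (0.0717 to 0.215). Ribosomal protein genes have many pseudogene copies.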

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

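Leaving out control 1 together with mutant 2, leaving out genes on the X and Y chromosomes, and adding 6 trypsinogen genes to the enzyme share were chosen after the data were seen; the other alternatives were planned. Prox1 kept its direction and its call in all 18 alternatives, with a log2 fold change of 1.56 to 1.78 when single libraries were left out, and the enzyme share kept its direction (-4.74 to -3.40 percentage points without single libraries). With the 6 trypsinogen genes added, 3 of which rose, the share differed by -2.25 points. The number of differing genes was 156 to 348 without single libraries (41 to 121 higher, 115 to 227 lower), and 131 of the 297 genes (33 higher, 98 lower) were kept in every such fit, which has fewer samples. It was 630 without control 1 and mutant 2 (221 higher, 409 lower) and 152 at a threshold of 0.01 (39 higher, 113 lower); with library size alone as scaling 246 were higher, because the median of all genes moved to 0.17. DESeq2 called 336 genes and limma-voom 270. With all 6 libraries, some calls near the threshold ended. A replicate block ended those of Atf3, Cldn4, Emr1, Clps, Pnlip, Vtn, Mrc1, C1qc and Rpl36 (edgeR adjusted p = 0.0615 to 0.174). Non-robust estimation ended those of Atf3, Ddit3, Cldn4, Emr1, Clps, Pnlip, Rpl36 and Gsta4 (0.0551 to 0.0737). Limma-voom ended those of Atf3, Cldn4, Emr1, Pnlip, Rpl36 and Gsta4 (adjusted p = 0.0576 to 0.113). DESeq2 ended that of Rpl36 (0.0982) and called Rbpjl (0.00118) and Krt19 (0.0204). No filter on low counts ended those of Ahsg and 1810009J06Rik (edgeR adjusted p = 0.0789 and 0.0588) and called Rbpjl (0.0336). The stricter filter ended those of Ddit3, Rpl36 and Gsta4 (edgeR adjusted p = 0.0512, 0.0532 and 0.0507). Lists called lower numbered 0 with an estimated correlation and 2 by fry. Lists called higher numbered 2 with library size alone, 2 with the stricter filter, 1 at a threshold of 0.01, 0 with an estimated correlation, 0 by fry and 2 to 7 without single libraries. With an estimated correlation the adjusted p was 0.403 for the digestive enzyme, acinar transcription factor and zymogen granule lists and 0.629 for macrophages. By fry the adjusted p was 0.0237 for the digestive enzyme and acinar transcription factor lists, 0.0677 for zymogen granules and 0.357 for macrophages. The camera adjusted p of macrophages was 0.414 without control 1 and mutant 2. Without those 2 libraries the fitted log2 fold changes of Cd79b, Glycam1, Ptprc and Ms4a1 turned to -2.43, -7.89, -1.42 and -3.75, mutant 2 being the library in which they were high; the value of Glycam1, at 0 counts in mutants 1 and 3, depends on the prior count. Leaving out single libraries gave -3.42 to 0.76 for Ms4a1. Directions also turned for the islet list (adjusted p = 0.732 without both, 0.000343 to 0.831 without single libraries), ER chaperones (0.00274 without both) and cholesterol synthesis (0.0255 to 0.883 without single libraries); the cause was not tested. Replicate numbers are shared by the groups, but same-numbered samples did not deviate together (correlations 0.08, 0.03 and -0.07); with a replicate block 250 genes were called, 228 of them among the 297. No gene symbol marked mitochondrial transcripts, so that alternative for the enzyme share gave no value, and lists were not recomputed under DESeq2, limma-voom or non-robust estimation, which camera does not use. At these depths and with 3 libraries per group, 25.8% of genes changed 1.5-fold were recovered in simulated data; depth was not varied.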

Other observations

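The tests on cell types and lymphoid tissue were planned before the data were examined, as was the count over splits. The comparison of these tests with the spread between libraries and the tests on glutathione transferases, neighbouring genes, Ctrl and trypsinogens were chosen after the results were seen.

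Some genes of glutathione S-transferases, which detoxify electrophiles, fell. Of 15 tested genes whose symbols start with Gst, 6 fell (Gstt3, Gstt2, Gstm2, Gstp1, Gsto1 and Gsta4, log2 fold changes from -1.51 to -0.58, n = 3 each) where 0.25 were expected from the share of falling genes. The other 9 did not pass, with log2 fold changes from -0.38 for Gstm5 to 0.25 for Gstm6. Among 534 tests over 267 symbol starts this had the smallest p (Fisher's exact test, one-sided, p = 8.37e-08, adjusted p = 4.47e-05), and Gst genes are related in sequence and partly clustered, so they are not independent. The start Pro was also called (Prom1, Prom2 and Prox1, higher, adjusted p = 0.00352), but it is no gene family and holds the gene of the transgene. With scaling by library size alone Gstm2, Gsto1 and Gsta4 no longer passed (edgeR adjusted p = 0.0643, 0.103 and 0.0702). Leaving out single libraries ended the calls of Gstm2 (control 2, mutant 1 or mutant 3, 0.0571 to 0.0621), Gstp1 (control 2, control 3 or mutant 3, 0.0599 to 0.103), and Gsto1 and Gsta4 (any but control 2, 0.0585 to 0.193).

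Called genes lay next to each other more often than chance gives. Of 278 called genes with a position, 35 had a called gene of the same direction within 50 kb, against 8.5 on average in 10000 shuffles of the calls over 11843 genes (permutation p = 1e-04, the smallest the shuffles can give). The pairs are not all independent, since they include related genes (1810009J06Rik, Gm2663 and 2210010C04Rik, Ang and Rnase1, Ahsg and Fetub, Gp2 and Umod, and Reg, Gst and Serpina genes) and the overlapping pairs Hmga2 with 9230105E05Rik and P2rx6 with Slc7a4. Pairs of genes not known to be related included Cel and Gtf3c5, and Ctrl and Psmb10, all lower.

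Ctrl and Psmb10 fell together in every mutant library, and Ctrl almost to 0. A lower share of acinar cells is argued against as the cause, since the other 24 tested digestive enzyme genes had a median log2 fold change of -0.52 (bootstrap interval -1.28 to -0.10) against -11.76 for Ctrl. A deletion or silenced stretch that reaches the flanking genes is argued against by their median of -0.10 within 200 kb, with 0 of 11 past the threshold. A local allele of Ctrl and Psmb10 shared by the mutant animals and an effect of Prox1 cannot be told apart: the highest mutant level of Ctrl was 6.95 CPM and the lowest control level 9507 CPM, so allele and group coincide, and reads were not analysed here.

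Prss1, Gm5771, Prss3 and Try4 were low in control 1 and in every mutant library (summed CPM 553 in control 1, 13298 and 13109 in controls 2 and 3, and 165 to 274 in the mutants), and Gm5409 was the opposite, at 617 CPM in control 1, 159 to 480 in the mutants and 3.65 and 2.79 in controls 2 and 3. For the low values of the mutants, the sex of the animals is argued against. Mutant libraries with Y-linked counts reached at most 274 CPM over these 4 genes. Controls 2 and 3, which also have Y-linked counts, reached at least 13109. For control 1 sex stays open, since the only low control was also the only library with high Xist and no Y-linked counts. Reads moved between near-identical trypsinogen copies may account for part of it in control 1. There the summed CPM of 12 trypsinogen genes was 10779 above the lower of controls 2 and 3. The other 8 copies together held 19837 CPM more than in the mean of those 2, against 12650 lost. The gain lay mainly in Prss2 (55221 CPM in control 1, 30185 and 37712 in controls 2 and 3). A higher Prss2 alone would give the same balance, so this balance cannot decide, and the mutants were not part of it. A segregating trypsinogen allele would move reads in the same way and was not tested. The fold changes of these 4 genes therefore rest on controls 2 and 3: the edgeR adjusted p of Prss1, Gm5771, Prss3 and Try4 were 0.246, 0.177, 0.384 and 0.25 with all libraries and 0.0382, 4.68e-07, 0.211 and 4.93e-06 without control 1. Prss1, Gm5771 and Try4 were also called by DESeq2 (1.87e-05, 1.81e-09 and 0.00155), by limma-voom (0.0439, 0.0401 and 0.0461) and without robust estimation (0.0152, 0.00577 and 0.0182), and Prss3 by DESeq2 (0.0153) and with a replicate block (0.00479).

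Macrophage genes were higher in the mutants as a list by camera, also when single libraries were left out (adjusted p = 2.02e-06 to 0.0197). They were not called with an estimated correlation (adjusted p = 0.629), by fry (0.357) or without control 1 and mutant 2 (camera adjusted p = 0.414). A lower share of acinar RNA, which would raise every other cell type alike, cannot be told apart from a change in macrophages: the macrophage median of 0.53 (bootstrap interval 0.38 to 0.65) lay above those of islet, duct, fibroblast and blood endothelium genes (-0.11, -0.12, 0.09 and 0.04) with no overlap of the intervals, but 0 of these 4 differences separated the mutant from the control libraries. Between libraries, the macrophage median minus these medians was higher in mutants by 0.70 (SE 0.40), 0.55 (0.30), 0.40 (0.29) and 0.47 (0.23), with exact two-sided permutation p of 0.2, 0.3, 0.3 and 0.2 (n = 3 each, smallest possible 0.1). Lymph node or spleen tissue dissected with the pancreas cannot be told apart either: the B cell median of 0.18 (interval -0.81 to 0.30) was under the planned bound of 0.265, but the macrophage median minus it differed by 0.85 (SE 1.11) between groups, and the T and NK median was 1.03. Both planned bounds were wrong in that intervals over members leave out the spread between libraries, and lymphoid tissue stays open for mutant 2 and controls 2 and 3, which held 279, 17 and 41 counts of the lymph node gene Glycam1 against 0 in the other 3 libraries.

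The number of genes that differed was set against other splits of the 6 libraries into 3 and 3. Of 10 splits only 1, the real one, gave 297 genes, and the highest of the others gave 1. With 10 splits no share under 0.1 is possible.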
